A study of Monomorium pharaonis with 23 samples.

How the data were processed

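Heads of Monomorium pharaonis workers were measured by RNA-seq in 9 forager and 14 nurse libraries, grouped by the labels' titles. The labels' protocols name a column-based RNA extraction kit, a transposase-based library kit and unstranded sequencing, with colonies kept at 27 degrees C, 50% relative humidity and 12 hours of light and 12 of dark. Reads were aligned with STAR 2.5.0b, per the submitters' processing notes; the counting tool, genome build and annotation are not given in the sources used here. The authors deposited 1 table of RPKM values for 12648 genes, and all 23 value columns were used. RPKM divides reads by gene length and by a library's read total, so a value carries no depth of its own, and a gene that takes many reads lowers the others in its library.

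Read totals, gene lengths and whole reads were recovered from the deposited RPKM values, which carry 6 significant digits, because the values of a gene are whole multiples of what 1 read is worth. A length was recovered for 12155 genes. Of the 12223 genes above 0 in any library, 68 were left without one, among them 2 of the 21 with a mean of at least 1000 RPKM, and 425 genes were at 0 in every library. Of the recovered values 99.9% were whole within 0.05 reads. The search largely ensures this, since it kept only lengths that made a gene's values whole, so the figure is no check of the recovery. Read totals ran from 3.68 to 31.3 M reads, where M stands for 1000000. A gene of 1 to 2 RPKM had a median of 8 to 35 reads in single foragers and 23 to 91 in single nurses. No library was a duplicate of another: over all 253 pairs, the lowest chi-square per degree of freedom was 12.1.

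Genes with at least 1 RPKM in at least 9 libraries were tested, 9622 in all. The test was limma on log2(RPKM + 1) with 1 term for task and an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are foragers minus nurses. The unit, RPKM, was the one assumed when the test was fixed. The tests, the filter, the rule for named genes and all but 5 alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 RPKM, rescaling to a common total, TMM and median-of-ratios factors computed from the RPKM values, quantile normalization, limma without trend, with a robust prior or with array weights, the replicate number as a block, a residual principal component, voom on the recovered reads, and leaving out each library. The 5 chosen after seeing the data were read depth and the share of reads in genes with a recovered length as covariates, libraries of 8 to 17 M reads alone, leaving out 3 libraries with under 50% of reads in such genes, and leaving out the 3 libraries with the highest Osi6.

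Identifiers were paired with the annotation of assembly GCF_013373865.1 ASM1337386v2, used only for symbols and for the order and spans of genes, since the authors' build is not given in the sources used here. It matched 10700 identifiers and left 1948 unmatched, and gave a symbol other than the identifier to 2. It carries no product descriptions, so none of the 40 gene lists fixed beforehand could be filled, and no gene list test was run, including the markers of cell types and body parts. The rule for this case named the 2 genes with the largest fold change each way among those past the threshold. Without strand, reads of overlapping genes cannot be told apart.

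The recovery was tested on simulated data of 4173 genes with known lengths and totals: totals were right to within 6.3e-06 percent, 99.5% of lengths were recovered and 98.8% of those were exact. The test of foragers against nurses was run on simulated values of 9633 genes. It called 91.0% of 100 genes changed 2-fold and 96.9% of 98 changed 4-fold, with 9 unchanged genes among 195 calls. The simulated genes were drawn independently, with 1 spread for both tasks and no effect of depth on expression. These rates therefore do not measure the false calls in the real data. Group means of library measures were compared by exact permutation tests. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.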

Results

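Head RNA of pharaoh ant (Monomorium pharaonis) workers was sequenced to compare workers doing different jobs. Foragers were caught while searching for food and nurses while tending larvae. There were 9 forager and 14 nurse libraries, made from polyadenylated RNA with an unstranded kit. The colonies held 10 queens, 300 to 400 workers and 300 to 400 brood. How many heads and which colony each library came from is not given in the sources used here, so p-values measure the spread between these libraries. Expression is given in RPKM, reads per kilobase of gene and per 1000000 reads of the library, for 12648 genes known by identifier.

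Foragers were sequenced less deeply than nurses. The read total behind the RPKM values was 8.15 ± 3.96 M reads in foragers (SD, n = 9) and 15.4 ± 7.52 M reads in nurses (SD, n = 14), a difference of -7.21 M reads, where M stands for 1000000 (two-sided exact permutation test, p = 0.00458, adjusted p = 0.0229). Single libraries ranged from 3.68 to 31.3 M reads. The share of reads in the 12155 genes with a recovered length was 57.6% ± 4.97 in foragers (SD, n = 9) and 58.2% ± 5.05 in nurses (SD, n = 14), and no difference was detected (exact permutation p = 0.775, adjusted p = 0.970). Each library's own 10 most abundant genes, which may differ between libraries, held 18.3% ± 2.40 of its summed RPKM in foragers (SD, n = 9) and 15.5% ± 2.25 in nurses (SD, n = 14, exact permutation p = 0.0110, adjusted p = 0.0276). Adjustment was over the 5 library measures compared. The number of genes at or above 1 RPKM and the summed RPKM gave exact permutation p-values of 0.970 and 0.836.

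**Figure D1:**
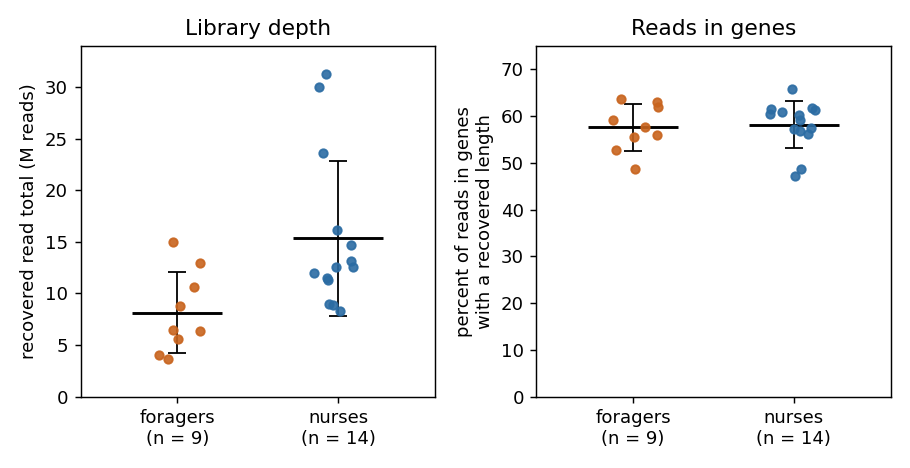
Recovered read total in M reads (left) and percent of reads in genes with a recovered length (right) for each library, one point per library, with the mean (line) and SD (bars) of each group. Foragers lie between 3.68 and 15.0 M reads and nurses between 8.31 and 31.3 M reads, while the shares of reads in genes overlap.

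The main comparison asks which genes differ in the head between foragers and nurses. LOC105841106 was the gene with the largest rise in foragers, at 69.5 ± 48.0 RPKM (SD, n = 9) against 4.60 ± 3.63 in nurses (SD, n = 14). LOC105833919 was at 54.0 ± 33.3 RPKM in foragers and 3.88 ± 3.25 in nurses. For both identifiers, the lowest forager lay above the highest nurse. Their values moved together within each task, with Pearson's r of 0.969 in foragers and 0.953 in nurses. They need not be independent results, and whether they share reads was not tested. In the other direction, LOC105830375 was at 952 ± 543 RPKM in nurses and 274 ± 402 in foragers, and LOC105829883 at 122 ± 81.2 in nurses and 27.8 ± 32.0 in foragers. Nurse 1 was the exception among nurses for both of these, with 19.1 and 9.60 RPKM, and 13 of 14 nurses lay above the forager median. It stood apart beyond these genes. On the first principal component of all tested genes (17.8% of the variance) nurse 1 lay at -22.4, beside forager 4 at -21.9. The next lowest nurse, nurse 7, lay at -0.12. In turn, foragers 1 and 9 lay among the nurses, at 6.76 and 10.4.

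On the log2(RPKM + 1) scale, which understates the change of low genes, LOC105841106 was higher in foragers by 3.64 (SE 0.33, limma adjusted p = 3.5e-07) and LOC105833919 by 3.50 (SE 0.33, limma adjusted p = 4.5e-07). LOC105830375 had a log2 fold change of -3.04 (SE 0.81, limma adjusted p = 0.0330) and LOC105829883 of -2.42 (SE 0.49, limma adjusted p = 0.00548). The call of LOC105830375 was lost in 14 of 43 alternative settings and that of LOC105829883 in 4 of 43, with adjusted p from 0.00346 to 0.491 and from 2.5e-04 to 0.351. With read depth as a covariate their log2 fold changes were -2.39 (limma adjusted p = 0.491) and -1.73 (limma adjusted p = 0.288).

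**Figure D2:**
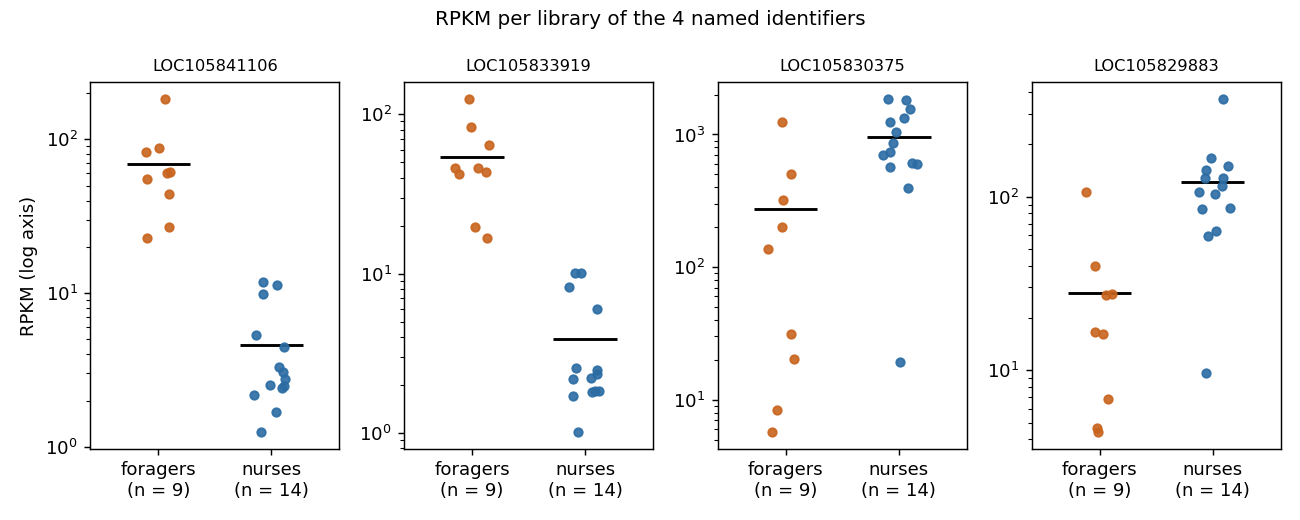
RPKM (log axis) of the 4 named identifiers in each library, one point per library, with the group mean as a line. For LOC105841106 and LOC105833919 no nurse reaches the lowest forager, whereas for LOC105830375 and LOC105829883 the groups overlap, with nurse 1 among the foragers.

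Across the 9622 genes tested, 169 were higher in foragers and 210 in nurses, 3.94% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). The genes higher in foragers had a median fold of 1.46 and those higher in nurses of 1.64. At least 2-fold differences were found for 27 and 47 of them, counts that ran from 9 to 31 and from 1 to 77 over 43 alternative settings. In 7 genes every forager lay above every nurse, and in 0 genes did every nurse lie above every forager; chance gives 0.0118 genes in each direction. All 7 were among the called genes. With the libraries rescaled by TMM factors the called genes were 154 and 354, and by median-of-ratios factors 172 and 360, mostly through more calls higher in nurses. Of the calls, 30.3% and 32.3% were then higher in foragers in place of 44.6%, while rescaling to a common total gave 44.7% and quantiles 48.5%.

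Fewer genes were called among libraries of like depth or with depth in the model, both chosen after seeing the data. Among the libraries of 8 to 17 M reads, 4 foragers and 11 nurses, limma called 9 genes higher in foragers and 1 in nurses; random sets of as many libraries gave a median of 71 calls, and 4 of 100 gave 10 or fewer. With depth as a covariate in all 23 libraries the counts were 17 and 4, and depths shuffled within groups gave a median of 90.5 calls. At an unadjusted p under 0.05 there were 935 and 822 genes, against 1612 without these changes and 481 by chance. LOC105841106 and LOC105833919 stayed past the threshold in all 43 alternatives, with adjusted p of at most 0.00187. Leaving out forager 5 or forager 3, the shallowest libraries, left 88 and 119 or 98 and 112 genes, while leaving out forager 4 gave 267 and 201, forager 6 276 and 199, and nurse 1 176 and 328.

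**Figure D3:**
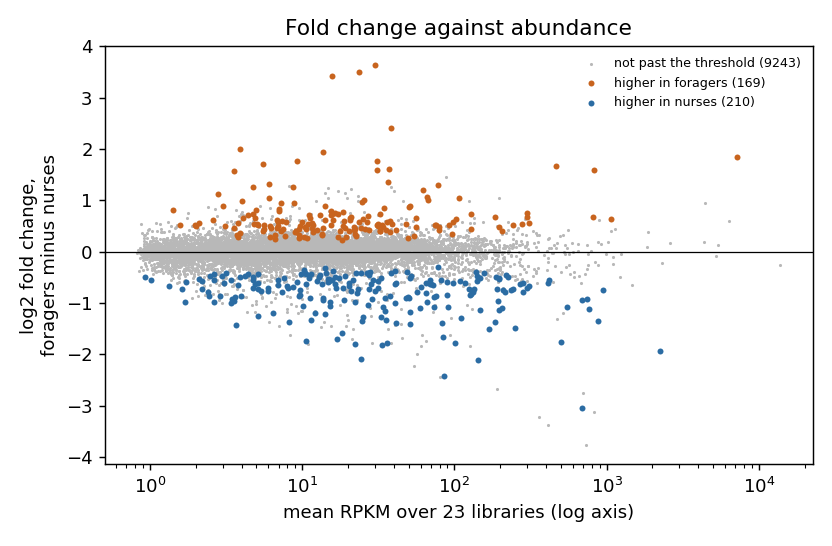
Log2 fold change, foragers minus nurses, against mean RPKM over the 23 libraries (log axis), one point per tested gene, with the 169 genes higher in foragers and the 210 higher in nurses in colour. Called genes span the range of abundance, and some genes with large fold changes, in grey, did not pass the threshold.

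Abundance was taken as the mean of the forager and the nurse mean, so that both groups weigh alike. Of the 210 genes higher in nurses, 22.4% lay at 100 RPKM or above, against 10.7% of the 169 higher in foragers (47 and 18 genes, Fisher's exact test over genes, two-sided, p = 0.00256, adjusted p = 0.00768). Among all 9622 tested genes, 488 lay there by the mean over all libraries, a smaller share than in either list. High abundance was therefore not a trait of the genes higher in nurses alone. At 20 RPKM the outcome turned on the weighting: 115 and 75 genes gave p = 0.0498 (adjusted p = 0.0747), and with the mean over all libraries 118 and 75 gave p = 0.0234 (adjusted p = 0.0351). No difference was detected at 500 RPKM, with 8 and 5 genes (p = 0.780, adjusted p = 0.780). The 3 limits and the weighting were chosen after the data were seen, and genes are not independent replicates. The most abundant gene higher in foragers ranked 2 of all genes by this mean (2 in foragers, 6 in nurses), at 12385 ± 3381 RPKM in foragers (SD, n = 9) and 3891 ± 2387 in nurses (SD, n = 14; limma adjusted p = 8.7e-04). The most abundant gene higher in nurses ranked 10 (27 in foragers, 8 in nurses), at 3131 ± 1321 RPKM in nurses (SD, n = 14) and 877 ± 510 in foragers (SD, n = 9; limma adjusted p = 8.7e-04). Together the genes higher in foragers made up 7.28% ± 1.30 of the summed RPKM in foragers (SD, n = 9) and 3.26% ± 0.97 in nurses (SD, n = 14). The genes higher in nurses made up 3.69% ± 0.81 in foragers and 7.30% ± 1.49 in nurses. Both lists were picked on these libraries, so the shares describe their size only.

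Only 2 genes had a symbol, and neither passed the threshold. Osi6 (LOC105828891), of the Osiris family of insect genes, which lie in a chromosomal cluster and are linked to cuticle formation, was at 2.52 ± 2.45 RPKM in foragers (SD, n = 9) and 151 ± 452 in nurses (SD, n = 14). Its nurse mean rested on nurse 13 with 1697 RPKM, nurse 4 with 305 and nurse 10 with 72.6, while all other libraries lay at or below 14.1. The log2 fold change was -1.62 (SE 1.00, limma adjusted p = 0.450). Ickin1-1 (LOC105834126) was at 89.3 ± 24.8 RPKM in foragers (SD, n = 9) and 76.3 ± 15.4 in nurses (SD, n = 14), a log2 fold change of 0.20 (SE 0.14, limma adjusted p = 0.495). These 2 genes were named after their values were seen.

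**Figure D4:**
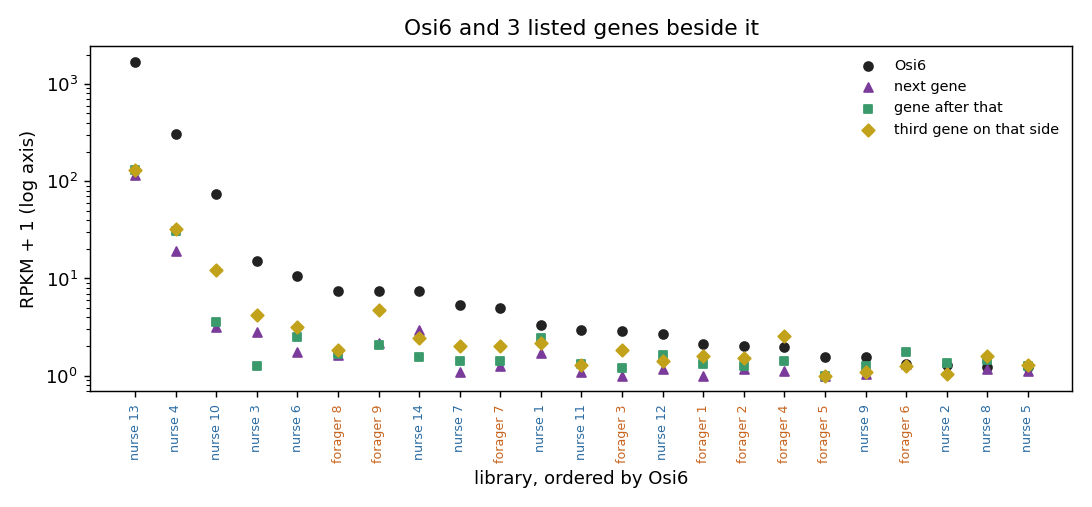
RPKM + 1 (log axis) of Osi6 and the 3 listed genes next to it on one side, in each library, ordered by Osi6; library names are orange for foragers and blue for nurses. The 4 genes are highest together in nurse 13, where Osi6 reaches 1697 RPKM, and in nurse 4.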

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

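The tests of depth, of the share of reads in genes, of other splits of the libraries and of Osi6 were chosen or worded after the result was seen; those of the spread were set after the larger SDs in foragers had been seen but before they were run, except the comparison with random sets of libraries and the doubled tail.

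Single foragers stood apart from the other 8 in 3 values, on the RPKM scale only. LOC105841106 was at 183 RPKM in forager 5, where the next forager had 88.3. LOC105830375 was at 1249 RPKM in forager 1, where the next had 501, and LOC105829883 at 107 in the same library, where the next had 39.8. Set against Dixon's critical value, the gap over the range was 0.591, 0.602 and 0.655 and past it in RPKM, but 0.353, 0.175 and 0.325 on the log2(RPKM + 1) scale used for the tests, where none is past it. The test was applied to both ends of 11 measures over the 9 foragers; chance flags about 1 in 20 groups, and the 14 nurses were not tested, since groups of more than 10 were left out by rule.

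That 379 genes differed between foragers and nurses was weighed against chance and depth. Of 100 splits of the 23 libraries into 9 and 14, 1 gave as many calls, the real one, and the highest other gave 39. That argues against chance if the libraries are independent, and 1 of 100 is the smallest share this draw can give. A colony shared between libraries, which is not given in the sources used here, and depth are not covered by these splits. Depth as the whole cause cannot be decided by the fold changes of the called genes. These genes were picked for their difference in the same libraries, which can keep the ratio of adjusted to unadjusted fold change high. The 21 genes still called with depth as a covariate argue against a linear effect of depth as their whole cause. They do not settle it for the other called genes. With depth as a covariate the fold changes of the 379 genes kept a median ratio of 0.83 (0.79 to 1.19 with shuffled depths). Among libraries of 8 to 17 M reads the ratio was 0.76 (0.75 to 1.27 in random sets of 4 foragers and 11 nurses). With the share of reads in genes as a covariate it was 0.99, and the calls rose to 708 and kept all 379. That share was 57.6% in foragers and 58.2% in nurses (exact permutation p = 0.775). A covariate so alike in both groups could hardly lower the fold changes, so this fit cannot decide whether the share is a cause. Depth as part of the cause stays open: the covariate left 21 calls, and 4 of 100 shufflings of the depths within groups left as few (median 90.5), as did 4 of 100 random sets beside the 10 calls at 8 to 17 M reads, and only 1 of 100 gave as low a ratio in either comparison. With task in the model, no single gene related to depth (limma, 0 at an adjusted p under 0.05; 349 at an unadjusted p under 0.05, where chance gives 481), but over the called genes 85.0% had a depth slope opposite in sign to the task difference, as high as in 1 of 100 shufflings (median 54.0%), so part of the difference may be depth; task stays open beside it.

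Foragers varied more than nurses in 73.2% of tested genes, with a median SD of 0.33 against 0.25 on the log2 scale. Chance cannot be told apart from a difference, since permuting the group labels of the residuals gave a p of 0.0553 by distance from 50%, as set beforehand, but of 0.0296 with the nearer tail doubled, where all but the outermost 1 in 20 permuted shares lay between 24.4 and 70.5%. The counting error of reads is argued against as the source only in the 3029 genes with a mean of at least 20 RPKM. There the share was 72.6% after the counting variance was subtracted. The median counting SD of these genes was 0.067 in foragers and 0.048 in nurses, against 0.31 and 0.25 after subtraction. Genes under 20 RPKM, with fewer reads, were not tested in this way, so counting error stays open for them. Reads were taken as independent, so noise from fewer distinct molecules was not removed and stays open. Shallow foragers cannot be told apart from other causes: the share was 52.8% among libraries of 8 to 17 M reads, under the 55% set as a bound beforehand, but all but the outermost 1 in 20 random sets of 4 foragers and 11 nurses gave 44.4 to 72.5%, so that bound was poorly placed.

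Osi6 was high in 3 nurse libraries, 870-fold over its median in nurse 13. Of its 10 nearest genes 4 had an r above 0.8 with Osi6, and the median r was 0.635 (0 of 1000 random genes as high, p = 0.001, the smallest the draw can give). As a median over the 10 genes, the relation rests on the highest libraries. The median rho was 0.272 (107 of 1000 random genes as high, p = 0.108), and the median r without the 2 farthest libraries was 0.111. For the next 3 genes alone, r with Osi6 was 0.908 to 0.972. Without the 3 highest libraries it was 0.419 to 0.815, where Osi6 lay at or below 14.1 RPKM. These r values of the next 3 genes were not tested against chance. Reads of Osi6 counted to its neighbours stay open, and with them a rise of Osi6 alone. The summed next 3 genes kept their ratio to Osi6 within 1.19 times, under the bound of 1.5 used for shared reads. That sum hides opposite moves, so it decides nothing. In nurse 13 the 3 genes were at 6.80, 7.57 and 7.55% of Osi6, and in nurse 10 at 2.99, 3.54 and 15.4%. Each gene's own ratio, looked at afterwards, varied by at least 2.04 times, past that bound (chi-square test of reads, p at most 7.9e-07). It varied by 2.04 to 2.28 times without nurse 4 and by 1.48 to 2.75 without nurse 13. Without nurse 10 it varied by only 1.14 to 1.38 times, so the outcome rests on that library. No biological explanation was tested.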

How the results depend on the processing

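Of 43 alternatives, 23 left out 1 library and 5 were chosen after seeing the data. In all 43, every called gene that was tested kept its sign. That was close to given, since the genes were called on these same libraries. Some settings, such as no filter, no trend and a robust prior, also leave the fold changes as they are. Scaling changed the counts of genes higher in foragers and nurses from 169 and 210 to 262 and 324 with a common total, to 354 higher in nurses with TMM and 360 with median-of-ratios factors, and to 284 higher in foragers with quantiles. A residual principal component, which by its construction removes spread within groups, gave 275 and 323. Samples numbered alike showed no clear pairing: 4 of 9 pairs had a correlation over 0.1 (from -0.34 to 0.43) and 1 of 9 foragers matched its own number best. These values were not tested against chance. The replicate block gave 44 and 22, and numbers 1 to 9 without a block 44 and 29. At an unadjusted limma p under 0.05 there were 1334 genes with the block and 1242 without it, so a weak pairing stays open. Among those added later, the depth covariate gave 17 and 4, libraries of 8 to 17 M reads 9 and 1, the share of reads in genes 393 higher in foragers, leaving out 3 libraries with few reads in genes 368 higher in nurses, and leaving out the 3 with the highest Osi6 93 higher in foragers. Leaving out 1 library gave 88 to 276 higher in foragers and 112 to 328 in nurses: 98 and 112 without forager 3, 267 higher in foragers without forager 4, 88 and 119 without forager 5, 276 higher in foragers without forager 6, and 328 higher in nurses without nurse 1. The cause was not tested. For these counts the other settings, voom on recovered reads included (133 and 157), stayed within 1.5 times. The genes at least 2-fold higher in foragers, 27, went to 17 with a pseudocount of 5, and the counts of 27 and 47 to 12 and 2 with the depth covariate and 9 and 1 at 8 to 17 M reads; those higher in nurses went to 11 with and 15 without the block, to 77 without libraries with few reads in genes, and to 74, 72 and 72 without forager 1, forager 9 and nurse 1. No gene list test (estimated correlation, fry or ranks) was run, since no list could be filled. Low genes of the shallow foragers rest on few reads: genes of 1 to 2 RPKM had a median of 8 reads in forager 5.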

Other observations

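Whether called genes neighbour each other was set as a test before it was run; the groups of variable genes and the pairs of identifiers were looked at after the data were seen.

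The genes that varied most within a task moved together in groups, as deviations from the mean of their task. Of the 40 tested genes with the largest SD within tasks (1.87 to 3.67 on the log2 scale, against a median of 0.29), 35 fell into 3 groups. These held 15, 10 and 10 genes correlated at over 0.5 on average, where 1000 shuffles gave at most 4 in a group. Each gene was shuffled on its own, so the shuffles show only that these genes were not independent. Other sets of 40 genes were not compared, so such groups are not shown to be particular to the most variable genes. The group of 15 was highest in nurses 3 and 4, on average 5.10 and 4.81 above the nurse mean on the log2 scale. A group of 10 that holds LOC105830375 deviated most upward in foragers 9 and 1, at 4.76 and 4.08 above the forager mean. It deviated most downward in nurse 1, at -4.48 from the nurse mean. In level the group was highest in nurse 10, with a median of 1358 RPKM over its genes, against 458 in forager 9 and 536 in forager 1. The other group of 10 was highest in nurse 7 at 3.82 and forager 7 at 3.04. LOC105830375 was the 1 gene of the 40 that passed the threshold between tasks.

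The named identifiers moved together within tasks. Between LOC105841106 and LOC105833919, Pearson's r was 0.969 within foragers (exact permutation p = 3.3e-04, n = 9) and 0.953 within nurses (permutation p = 4.0e-05, n = 14), with Spearman's rho of 0.850 and 0.837 (permutation p = 0.00607 and 3.4e-04). Between LOC105830375 and LOC105829883, r was 0.965 within foragers (exact permutation p = 1.1e-05, n = 9) and 0.821 within nurses (permutation p = 0.0216, n = 14), with rho of 0.983 and 0.574 (permutation p = 5.0e-05 and 0.0337). Adjusted over the 4 relations, the p-values of r were 4.3e-04, 8.0e-05, 4.4e-05 and 0.0216. Without the 2 libraries farthest from the median, r was 0.928, 0.919, 0.933 and 0.283, so the last relation rests on those libraries. LOC105830375 and LOC105829883 lie 13 listed genes apart on the same chromosome in the reference assembly, and the other 2 identifiers were not placed. Whether LOC105841106 and LOC105833919 share reads was not tested and stays open, so they need not be independent results.

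Called genes tended to lie next to genes called in the same direction. Of 343 called genes placed on a chromosome, 26 neighbouring pairs shared a direction, where 10000 shuffles of the calls gave a mean of 6.83 (one-sided permutation p = 0.0001, the smallest they can give), and 4 pairs were opposite, where shuffles gave 6.76. Of the 26 pairs, 14 were higher in foragers and 12 in nurses. Reads of overlapping gene models cannot be told apart without strand. Overlaps in the reference assembly are argued against as the whole source, since 20 pairs were left without overlapping spans, where shuffles gave 5.85. The models used for counting may overlap elsewhere, since the authors' annotation is not given in the sources used here. Reads shared between neighbouring copies of a gene were not tested and stay open.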
